A study of Homo sapiens with 6 samples.

How the data were processed

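PolyA RNA of 6 libraries from the SKK-1 line was sequenced, 3 from cells in the lowest 10% and 3 from cells in the highest 10% of long-chain fatty acid uptake. The deposited count table held whole-number counts per Ensembl gene, which the authors made by quantifying transcripts with Salmon against hg19, per the submitters' processing notes; the versions and the gene annotation are not given in the sources used here. The deposited normalized table held a signal on the scale of counts, which equalled each count divided by 1 median-of-ratios size factor per library, as tested on the values. Columns headed HGH were read as the HIGH libraries. Identifiers were given symbols from an Ensembl table, and 8102 of 37931 had none. No strand information was given, so counts of genes that overlap others are less certain. Gene positions are not given because the builds of the counts and of the annotation differ.

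Genes were kept by filterByExpr (15826 of 25035 with any count), scaled by TMM and tested with the two-sided quasi-likelihood F test of edgeR 4.0.16 in R 4.3.3, HIGH against LOW, with Benjamini-Hochberg adjustment over all tested genes and a threshold of 0.05. Values are CPM, counts scaled to a common TMM-adjusted library size. Gene lists written before the data were examined were tested with camera of limma 3.58.1 on log-CPM (prior count 2) at a preset correlation of 0.01. An estimated correlation and fry were set beside it, and p-values were adjusted over the lists with at least 5 tested members. With an estimated correlation camera uses the 4 residual degrees of freedom, which raises p by itself. A threshold missed there does not by itself mean that the genes of a list are correlated. A gene without a count in HIGH was given a lower bound against a floor of 3 counts over the group, and one with 1 to 3 counts a ratio with an exact binomial 95% interval; both cover counting error only. The labels do not say that the libraries came from separate cultures, so p-values measure the spread between libraries.

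The genes to be named were set by a rule before the data were examined. They were the 12 largest rises and the 12 largest falls in log2 fold change that passed the test with a mean of at least 5 CPM, a gene symbol and no overlap between the groups, up to 4 members of each list with the smallest p, and CD36, CD34, CD38, KIT, PLIN2, CPT1A, FASN, SCD and MKI67 in every case. XIST and genes of the Y chromosome stayed in the counts and tests but were never listed or named.

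The labels do not say whether equal replicate numbers mark one sort. After the group means were removed, LOW and HIGH libraries of equal number correlated at 0.72, 0.62 and 0.44 across genes, and no other pair exceeded 0.18. A fit with the number as a block was therefore set beside the unblocked one. Deviations within a group cancel out, so the low values of the other pairs follow in part from the high ones. The other alternatives were RLE, upper-quartile and library-size scaling, no filter and a filter at a mean of 5 CPM, DESeq2 1.42.0, limma-voom, limma on the deposited normalized values and leaving out each library. Each test was tried on its own data, simulated at the observed depth with the spread of its own fit. The unblocked test recovered 4% of 2-fold, 58% of 4-fold and 94% of 16-fold changes, and the blocked one 58%, 92% and 100%. Unchanged genes made up 7 of 86 simulated calls without and 20 of 163 with the block. Only the data for the blocked test held an effect of the replicate number, of an assumed size, so these rates do not compare the tests. Figures were drawn with matplotlib 3.10.9.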

Results

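SKK-1 is a human cell line derived from a patient with myelodysplastic syndrome that had progressed to secondary acute myeloid leukaemia. Its cells were sorted by flow cytometry on how much long-chain fatty acid they took up, and polyA RNA was sequenced from the lowest 10% (LOW, 3 libraries) and the highest 10% (HIGH, 3 libraries) of the parental population. The comparison asks how cells of one line at opposite ends of fatty acid uptake differ in metabolism and in the surface antigens and stem cell genes they express. LOW 1, 2 and 3 held 34805589, 36990247 and 38099718 counts over 37931 gene identifiers, and HIGH 1, 2 and 3 held 31357919, 37663475 and 35884301. On log expression, the first principal component held 54.7% of the variance and separated LOW from HIGH, and the second held 28.7% and set both libraries numbered 1 apart from the other 4. Cytosolic ribosomal protein genes took 11.2% of the counts in LOW 1 and 11.1% in HIGH 1, against 6.17% to 7.50% in the other libraries.

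HIGH cells lacked or nearly lacked transcripts of many genes that LOW cells expressed, and the reverse was rare. Of 15826 genes tested, 731 were lower and 85 were higher in HIGH (edgeR quasi-likelihood test, Benjamini-Hochberg adjusted p under 0.05), so that 89.6% of the calls were falls. Among them, 454 fell and 22 rose by more than 16-fold. Among the genes that were listed, 164 had at least 1 CPM in every LOW library and at most 3 counts over the 3 HIGH libraries, and each of these passed the test. Across all tested genes, 17.8% did not overlap between the groups, where chance gives 10% if all libraries are exchangeable. Libraries of equal number were correlated, so the 10% is only a guide. With the replicate number as a block, 1785 genes fell and 1442 rose, so that 55.3% of calls were falls, and all 816 genes called without the block were called again in the same direction. Without LOW 1, LOW 2, LOW 3, HIGH 2 or HIGH 3 the rises numbered 43, 46, 26, 48 and 42, and without HIGH 3 the falls numbered 485.

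**Figure D1:**
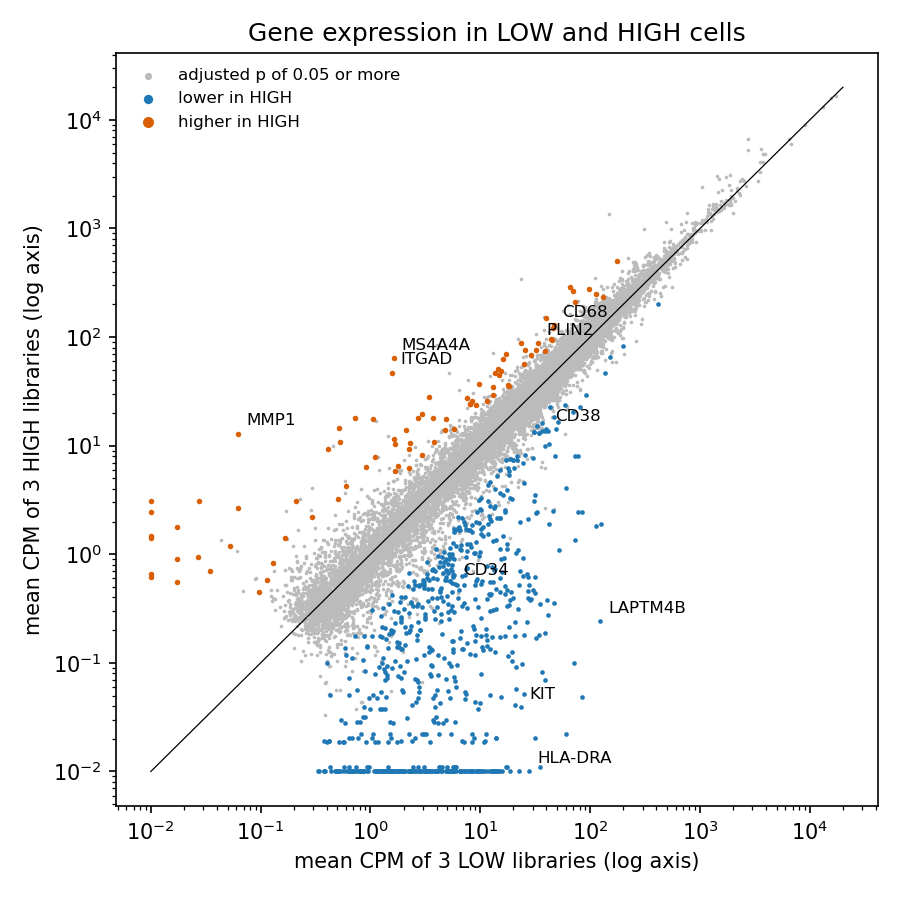
Mean expression of each tested gene in the 3 LOW (x axis) and 3 HIGH (y axis) libraries, in CPM on log axes, with means under 0.01 CPM drawn at 0.01. Blue points are the genes lower and orange points the genes higher in HIGH at an adjusted p under 0.05, grey points the rest, and the line marks equal expression; many genes at 1 to 100 CPM in LOW lie at the bottom edge, and few lie at the left edge.

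MMP1, MS4A4A, ITGAD, FAP and TLR2 were among the genes with the largest rises. MMP1, an interstitial collagenase, went from 0.0623 ± 0.0873 to 12.9 ± 11.3 CPM (SD, n = 3), a log2 fold change of 7.63 (SE 1.34). MS4A4A, a macrophage surface protein, went from 1.62 ± 0.869 to 64.1 ± 17.3 CPM, a 39.4-fold rise. ITGAD, an integrin alpha chain that pairs with CD18 on leukocytes, rose 30.1-fold to 47.1 ± 13.1 CPM, and TLR2, a receptor for bacterial lipoproteins, rose 24.8-fold to 18.0 ± 6.94 CPM. The cell surface protease FAP rose 28.4-fold, FHAD1 20.1-fold and the creatine synthesis enzyme GATM 8.13-fold. ART3, LMO1, HSPA6 and SEMA6A rose 7.02-fold, 6.69-fold, 6.64-fold and 6.31-fold. With 1 library fewer, some of these calls were lost while the direction stayed. MMP1 missed the threshold without LOW 1, LOW 3 or HIGH 3 (edgeR adjusted p = 0.0578, 0.103 and 0.0622), FAP without LOW 3 or HIGH 3 (0.0852 and 0.0528), and HSPA6 without LOW 1, LOW 2 or LOW 3 (0.0732, 0.0646 and 0.103). ART3 missed it without any single library other than HIGH 1, at adjusted p from 0.0639 to 0.184, and with a filter at a mean of 5 CPM (0.0884). Without both libraries numbered 1, HSPA6 was at 0.057. Without LOW 2 and without HIGH 2 the log2 fold change was 9.63 and 6.79 for MMP1 and 5.68 and 4.23 for FAP, and without HIGH 2 it was 2.06 for HSPA6.

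The largest falls ended at or near zero. HLA-DRA, the alpha chain of an MHC class II molecule, stood at 27.9 ± 16.6 CPM in LOW and had no count in HIGH, which puts it at least 922-fold lower against a floor of 3 counts over the group. The metalloprotease gene ADAMTS10, the transcription factor MYCN, DYNLT5, the platelet and endothelial protein gene MMRN1 and the phosphorylase kinase subunit PHKA1 likewise had no count in HIGH, and were at least 482-fold, 459-fold, 400-fold, 359-fold and 351-fold lower. PDLIM1 went from 84.3 ± 55.2 to 0.0487 ± 0.0136 CPM. NRIP1, a nuclear receptor corepressor, had 6797 counts over the LOW and 2 over the HIGH libraries, a ratio of 3017 with a 95% counting interval from 835 to 24915. SERPING1 also had 2 counts over the HIGH libraries (ratio 1562, interval 432 to 12905). EDIL3, POGLUT2 and the epithelial keratin gene KRT18 had 1 count each, with ratios of 3507 (629 to 138560), 1749 (313 to 69103) and 1718 (308 to 67876). Without LOW 1, PHKA1 was at least 228-fold lower, the ratios of NRIP1 and SERPING1 were 1978 and 912, and the log2 fold change of PDLIM1 was -9.96. Without HIGH 1, EDIL3, NRIP1, POGLUT2 and KRT18 had no count in HIGH and were at least 819-fold, 1409-fold, 408-fold and 401-fold lower. Without HIGH 2 and without HIGH 3 the bound of HLA-DRA was 600-fold and 598-fold, and here and below every other bound of a gene without a count in HIGH fell by 1.53 to 1.54 times, through the lost depth. The ratios of NRIP1, EDIL3, POGLUT2 and KRT18 fell likewise, and without HIGH 2 that of SERPING1 was 1018. Reads of HLA genes can be split among copies on alternative haplotypes, so the level of HLA-DRA is less certain than the others.

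Genes of stem and progenitor cells were lower in HIGH. Of the 15 tested genes of the LSC17 leukaemia stemness score, 8 fell and none rose, and 13 fell when adjusted over the list alone. The list's median log2 fold change was -3.46, and camera placed it below the other genes (adjusted p = 1.76e-17, and adjusted p = 0.0303 with an estimated correlation). With the replicate block 13 fell, and camera with both the block and an estimated correlation gave an adjusted p = 0.566. That camera test rests on 2 residual degrees of freedom and called none of the 44 lists. Here and below it therefore cannot decide whether a list shifted. LAPTM4B, a lysosomal membrane protein gene, fell from 121.9 ± 20.98 to 0.242 ± 0.0765 CPM (log2 fold change -8.97, SE 0.35). The adhesion receptor ADGRG1 fell from 5.63 ± 1.22 to 0.126 ± 0.0537 CPM, and NYNRIN from 15.5 ± 4.05 to 0.0485 ± 0.0578 CPM. Of 39 tested haematopoietic stem cell genes, 21 fell and none rose, and 23 fell adjusted over the list alone, while with the block 26 fell and 4 rose. This list's camera adjusted p was 1.76e-17, with an adjusted p = 0.262 with an estimated correlation. KIT, the stem cell factor receptor, fell from 23.4 ± 11.1 to 0.0392 ± 0.0149 CPM (log2 fold change -9.09, SE 0.59). The transcription factor TAL1 fell from 36.5 ± 8.48 to 0.0818 ± 0.0715 CPM, and ANGPT1, which encodes the TIE2 ligand angiopoietin, from 34.4 ± 14.1 to 0.179 ± 0.0856 CPM. Without HIGH 3 the log2 fold change was -9.68 for NYNRIN and -8.18 for TAL1.

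Of 36 tested antigens used in leukaemia immunophenotyping, 10 fell and none rose. Adjusted over the list alone, 12 fell and 1 rose, and with the replicate block 14 fell and 5 rose. The camera adjusted p was 0.000181, with an adjusted p = 0.262 with an estimated correlation. CD34, the antigen of stem and progenitor cells, fell from 5.90 ± 0.973 to 0.537 ± 0.566 CPM (log2 fold change -3.46, SE 0.75, edgeR adjusted p = 0.0446). CD38, an ectoenzyme of committed progenitors, fell 2.79-fold from 39.9 ± 7.93 to 14.3 ± 3.11 CPM (adjusted p = 0.0179). CD200 fell 21.9-fold, and MME, which encodes CD10, fell 80.1-fold. The CD34 call was lost without any single library other than HIGH 1, at adjusted p from 0.0921 to 0.166, and the CD38 call without LOW 2, LOW 3 or HIGH 3 (0.0742, 0.0886 and 0.106). The log2 fold change of CD34 was -4.78 without HIGH 1, and that of MME -5.66 without LOW 1.

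Neutrophil and monocyte genes were shifted the other way. Of 41 tested, 4 rose and none fell, and 6 rose and 1 fell adjusted over the list alone. With the replicate block 20 rose and 2 fell. The median log2 fold change was 0.58 (camera adjusted p = 0.0012, and adjusted p = 0.552 with an estimated correlation), and the list missed the threshold without HIGH 2 (camera adjusted p = 0.104). CD68, a lysosomal glycoprotein of monocytes and macrophages, rose from 47.0 ± 4.45 to 129 ± 17.3 CPM (log2 fold change 1.46, SE 0.20). ITGAM, which encodes CD11b, rose from 14.9 ± 2.29 to 44.4 ± 5.69 CPM (1.58, SE 0.23). KLF4, a transcription factor of monocyte differentiation, rose 2.77-fold, and its call was lost without any single library (edgeR adjusted p from 0.06 to 0.205) and passed in 5 of 16 alternatives, missing the threshold also with upper-quartile scaling, library-size scaling, no filter, a filter at a mean of 5 CPM and without both libraries numbered 1 (0.0629, 0.0582, 0.0626, 0.112 and 0.138).

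**Figure D2:**
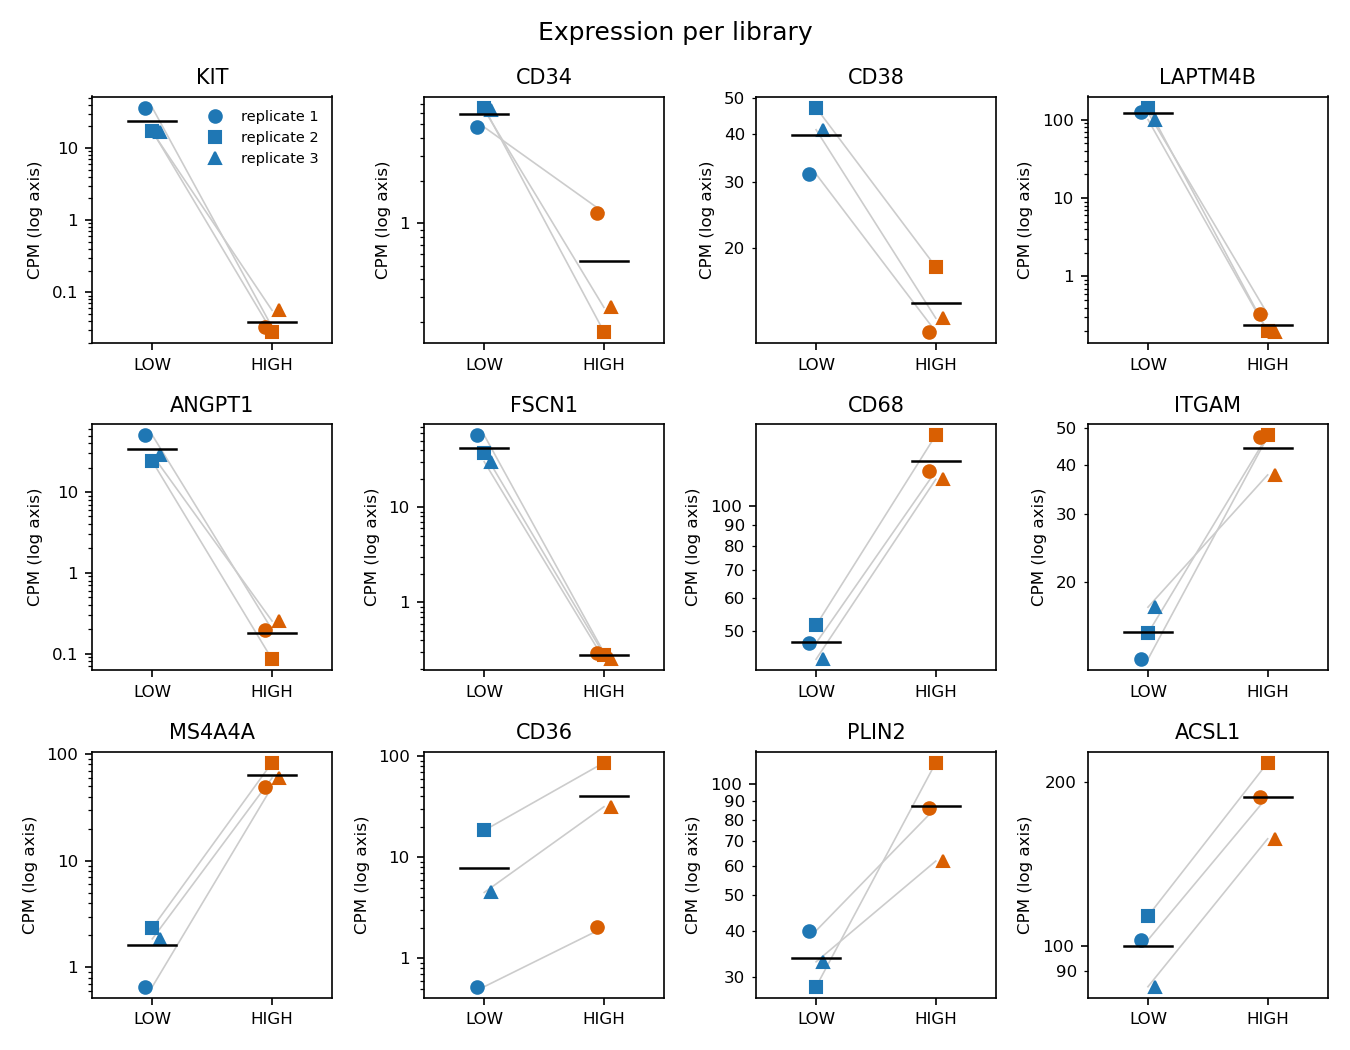
Expression of 12 named genes in each library, in CPM on log axes. Blue symbols are LOW and orange symbols HIGH libraries, circles, squares and triangles are replicates 1, 2 and 3, grey lines join equal numbers and black bars are group means; CD36 spans more between numbers than between groups, while KIT, LAPTM4B, ANGPT1 and FSCN1 do not.

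Markers of several other lineages were among the falls. Lists share members, so their calls are not separate results. ANGPT1 is in the stem cell and megakaryocyte lists, and MMRN1 in the LSC17 and megakaryocyte lists. KIT is in the stem cell, immunophenotype and mast cell lists. Of 24 tested megakaryocyte and platelet genes 9 fell and 1 rose (10 and 1 adjusted over the list alone, and with the block 11 and 4), and of 14 dendritic cell genes 5 fell and none rose (the same adjusted over the list alone, and with the block 7 and 1). Of 17 T and NK cell genes 5 fell and none rose (6 adjusted over the list alone), and of 13 stromal and endothelial genes 5 fell and none rose (6 fell and 1 rose adjusted over the list alone, and with the block 7 and 2). The camera adjusted p of these 4 lists were 6.49e-05, 3.6e-05, 0.0022 and 0.0012. None held with an estimated correlation, where the adjusted p were 0.262, 0.164, 0.312 and 0.337, and the megakaryocyte list missed the threshold without the 164 genes nearly absent from HIGH (camera adjusted p = 0.361). SELP, the platelet and endothelial P-selectin, had no count in HIGH and was at least 320-fold lower, as was the T cell antigen CD7, at least 174-fold lower. FSCN1, which encodes the actin bundler fascin, fell from 41.51 ± 14.03 to 0.278 ± 0.0226 CPM, and IL7R, the interleukin-7 receptor, from 24.5 ± 4.25 to 0.929 ± 0.695 CPM. FLT3 fell 65.9-fold, the keratin gene KRT8 17.4-fold and PDGFRB 10.1-fold; PDGFRB missed the threshold without HIGH 2 or HIGH 3 (edgeR adjusted p = 0.0599 and 0.0607). Without LOW 1 CD7 was at least 104-fold lower and the log2 fold changes of FLT3 and KRT8 were -5.37 and -3.44, and without HIGH 2 that of IL7R was -5.44.

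Of 12 B cell genes 3 fell and none rose, also adjusted over the list alone (with the block 4 and 2), but the list missed the threshold (camera adjusted p = 0.0521). It was called lower with RLE scaling (0.0489), without LOW 1, LOW 2, HIGH 1, HIGH 3 or both libraries numbered 1 (0.0271, 0.0244, 0.0212, 0.028 and 0.0153) and by fry (0.0241). The list was not called with the block or with an estimated correlation (camera adjusted p = 0.164 and 0.543). IGHM had no count in HIGH and was at least 42.3-fold lower. Mast cell, basophil and eosinophil genes went both ways, with 3 falls and 1 rise among 17 (5 and 1 adjusted over the list alone, and with the block 7 and 2; camera adjusted p = 0.014, and adjusted p = 0.262 with an estimated correlation). KIT and the histidine decarboxylase gene HDC were among the falls, and the tryptase gene TPSAB1 rose from 39.3 ± 5.88 to 151 ± 58.6 CPM. Reads of TPSAB1 can be shared with near-identical tryptase copies. The mast cell list missed the threshold without LOW 2 and with a filter at a mean of 5 CPM (camera adjusted p = 0.0523 and 0.136), TPSAB1 without LOW 1, LOW 3 or both libraries numbered 1 (edgeR adjusted p = 0.0639, 0.0832 and 0.0506), and HDC without LOW 2, LOW 3 or HIGH 3 (0.0599, 0.0706 and 0.113). Of 25 erythroid genes, 2 fell and none rose (4 fell adjusted over the list alone, and with the block 6 fell and 1 rose). The erythroid list's camera adjusted p was 0.128, 0.166 with the block, 0.38 with an estimated correlation and 0.0217 with no filter, and fry gave 0.0145. TRIM58 fell 6.21-fold, and the carbonic anhydrase gene CA2 had no count in HIGH and was at least 84.6-fold lower. Without LOW 1 the bounds were 51.3-fold for CA2 and 27.0-fold for IGHM, and the log2 fold change of HDC was -6.81 without HIGH 1 and -4.57 without HIGH 2.

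Interferon-induced genes included 6 falls and no rise among 40 tested (7 falls adjusted over the list alone), and the list as a whole missed the threshold (camera adjusted p = 0.0521). With the block 12 fell and 2 rose (camera adjusted p = 0.0221, and adjusted p = 0.572 with an estimated correlation). The list was also called lower with RLE scaling, no filter and a filter at a mean of 5 CPM (0.0489, 0.0164 and 0.0432), without LOW 2, HIGH 1 or both libraries numbered 1 (0.0327, 0.0212 and 0.00974), without the 164 genes nearly absent from HIGH (0.0269) and by fry (0.0136). The antiviral membrane protein IFITM3 fell from 112 ± 32.4 to 1.83 ± 0.214 CPM (log2 fold change -5.93, SE 0.32), and IFITM1 fell 13.3-fold; near-identical copies can share reads of these genes. XAF1 fell 5.76-fold and missed the threshold without LOW 3 or HIGH 2 (edgeR adjusted p = 0.0593 and 0.0559). Of 27 p53 target genes 5 fell and none rose, also adjusted over the list alone, and with the block 12 fell (camera adjusted p = 0.0173, and adjusted p = 0.543 with an estimated correlation). TP53I3 had no count in HIGH and was at least 77.8-fold lower, and SESN1 fell 2.73-fold. The p53 list missed the threshold without LOW 1, without the 164 genes nearly absent from HIGH and with a filter at a mean of 5 CPM (camera adjusted p = 0.0759, 0.0683 and 0.138), and SESN1 without any single library other than HIGH 1 (edgeR adjusted p from 0.0605 to 0.0965) and without both numbered 1 (0.063).

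Genes that handle fatty acids went both ways. Of 19 tested genes of fatty acid uptake and activation 2 fell and none rose (2 fell and 1 rose adjusted over the list alone; camera adjusted p = 0.304), while with the replicate block 7 rose and 2 fell. The list's median log2 fold change was 0.14 and its mean -0.21. It was called higher with a filter at a mean of 5 CPM and without HIGH 1 (camera adjusted p = 0.0489 and 0.0212), and had an adjusted p = 0.708 with an estimated correlation in the fit of all libraries. CD36, a scavenger receptor that imports long-chain fatty acids, stood at 0.522, 18.4 and 4.47 CPM in LOW 1, 2 and 3 and at 2.01, 86.1 and 31.6 CPM in HIGH 1, 2 and 3. It was higher in HIGH within each of the 3 numbered pairs, with a log2 fold change of 2.36 (SE 1.41, edgeR adjusted p = 0.673) that passed only with the replicate block (2.41, SE 0.19, adjusted p = 0.000762). The acyl-CoA synthetase ACSL1 was at 100.04 ± 14.77 and 187 ± 29.7 CPM (adjusted p = 0.077, 0.00119 with the block and 0.00369 with DESeq2), and the transporter SLC27A2 was at 6.38 ± 2.34 and 15.3 ± 6.07 CPM (0.237, 0.00665 and 0.0486). The members that fell were SLC27A6, another fatty acid transporter, which had no count in HIGH and was at least 113-fold lower, and ACSL6, which fell 4.32-fold. ACSL6 missed the threshold without any single library (adjusted p from 0.0524 to 0.115) and without both numbered 1 (0.0695).

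Among 22 tested genes of lipid storage and lipolysis, 2 rose and none fell, also adjusted over the list alone, and with the block 3 rose and 1 fell. Camera's adjusted p was 0.0521 without and 0.0426 with the block, and the latter became an adjusted p = 0.572 with an estimated correlation. The list was also called higher with library-size scaling, with no filter, without HIGH 3 and by fry (adjusted p = 0.0492, 0.0217, 0.0331 and 0.0162). PLIN2, the coat protein of lipid droplets, rose from 33.8 ± 5.94 to 87.5 ± 26.2 CPM (log2 fold change 1.37, SE 0.28, edgeR adjusted p = 0.0343), and the monoacylglycerol lipase MGLL rose 1.91-fold (adjusted p = 0.0459). PLIN2 missed the threshold without any single library other than HIGH 3 (adjusted p from 0.0624 to 0.165), with a filter at a mean of 5 CPM (0.082) and without both libraries numbered 1 (0.0977). MGLL missed it without any single library (0.106 to 0.176), and with upper-quartile scaling, library-size scaling, no filter, that filter and without both libraries numbered 1 (0.0983, 0.092, 0.0754, 0.138 and 0.0973). None of 38 fatty acid oxidation genes passed the test, also adjusted over the list alone (camera adjusted p = 0.102). CPT1A, which admits long-chain acyl groups to mitochondria, was at 119.7 ± 3.07 CPM in LOW and 87.0 ± 15.4 CPM in HIGH (adjusted p = 0.448, and 0.0416 with the block). Of 26 fatty acid synthesis genes, the elongase gene ELOVL6 alone fell, also adjusted over the list alone, from 19.4 ± 3.40 to 0.105 ± 0.0625 CPM, while with the block 5 rose and 4 fell (camera adjusted p = 0.954, median log2 fold change 0.06, mean -0.22). FASN, the fatty acid synthase, was at 306 ± 121 and 459.6 ± 165 CPM (adjusted p = 0.752, and 0.04 with the block). The desaturase SCD was at 1284 ± 311 and 1278 ± 520 CPM (adjusted p = 0.998).

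**Figure D3:**
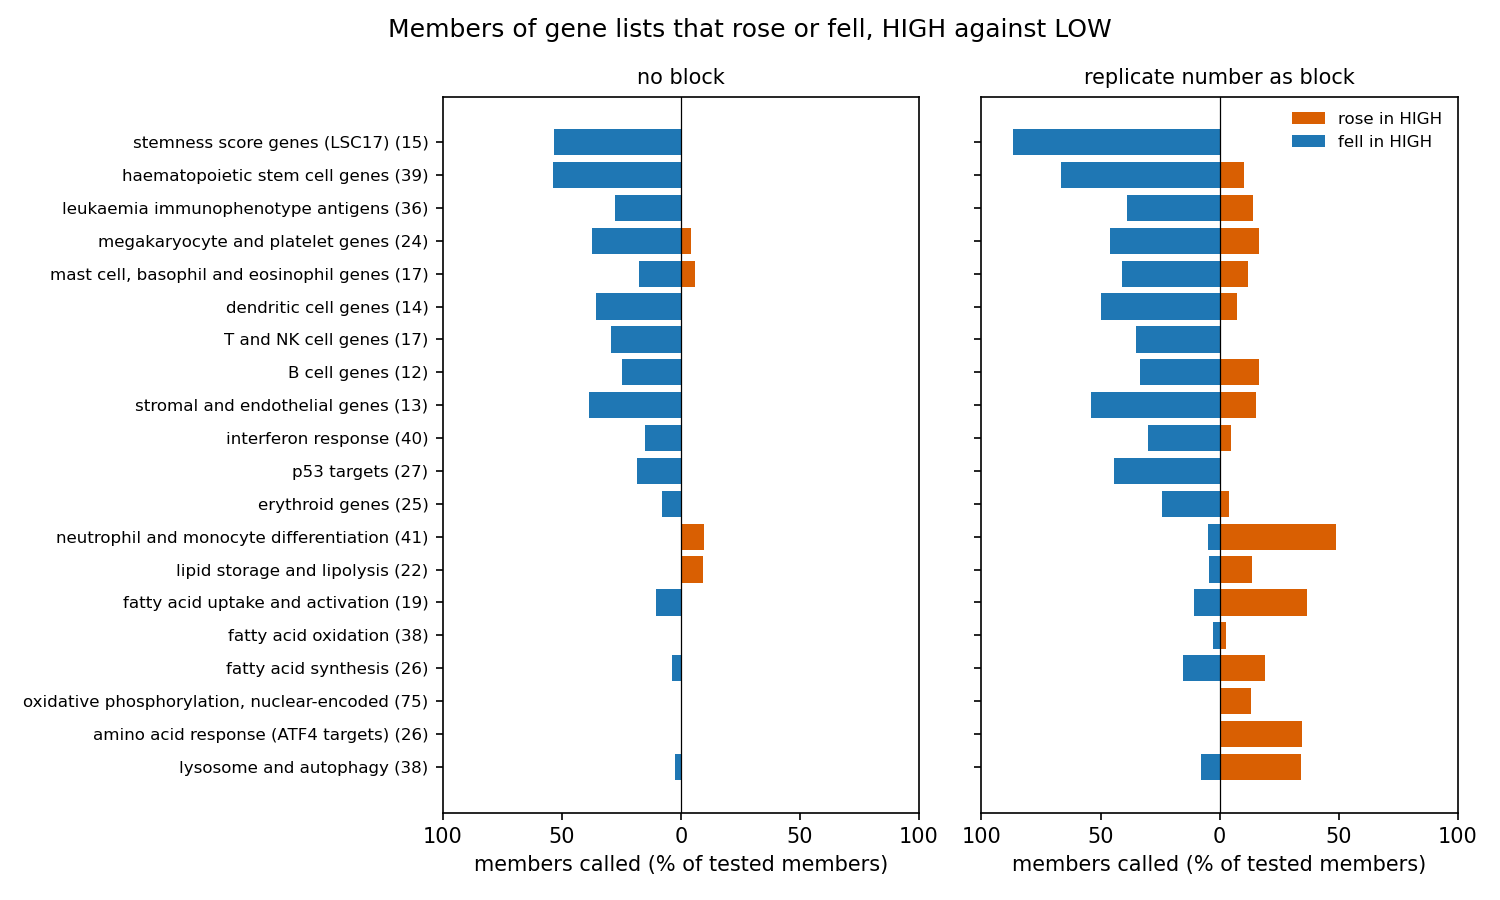
Share of the tested members of 20 gene lists that rose (orange, to the right) or fell (blue, to the left) in HIGH, in percent, without a block (left) and with the replicate number as a block (right); the number of tested members stands after each name. Stem cell lists lie to the left in both panels, and neutrophil and monocyte genes to the right, with 4 members of 41 rising without and 20 with the block.

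No nuclear-encoded gene of oxidative phosphorylation passed the test among 75, also adjusted over the list alone. The list's median log2 fold change was 0.15 (camera adjusted p = 0.0022, and adjusted p = 0.7 with an estimated correlation), and 10 of its members rose with the block. NDUFB9 of complex I was at 189 ± 40.5 and 353 ± 58.3 CPM (edgeR adjusted p = 0.113, 0.00119 with the block and 0.00774 with DESeq2), and COX6C of complex IV at 121 ± 18.6 and 196 ± 28.9 CPM (0.197, 0.00568 and 0.0486). Amino acid response genes under ATF4 had a median of 0.39 with no member of 26 passing, also adjusted over the list alone, and 9 rising with the block (camera adjusted p = 0.0012, and adjusted p = 0.333 with an estimated correlation). TRIB3 was at 81.1 ± 29.5 and 173 ± 22.2 CPM (adjusted p = 0.105, 0.00311 with the block and 0.00883 with DESeq2), and passed without LOW 2 (0.036). CEBPB was at 18.5 ± 7.92 and 45.2 ± 15.3 CPM (0.164, 0.00105 with the block and 0.0252 with DESeq2). Of 38 lysosome and autophagy genes 1 fell and none rose, also adjusted over the list alone, while with the block 13 rose and 3 fell (camera adjusted p = 0.014, and adjusted p = 0.262 with an estimated correlation). The cathepsin gene CTSD was at 1485 ± 82.2 and 2884 ± 311 CPM (edgeR adjusted p = 0.0702, 0.00155 with the block and 2.94e-05 with DESeq2). CTSH went the other way, with a log2 fold change of -1.41 (edgeR adjusted p = 0.0831, 0.00326 with the block and 0.00764 with DESeq2). The oxidative phosphorylation list missed the threshold without HIGH 2 (camera adjusted p = 0.0995).

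Of 15 tested drug efflux transporters 3 fell and none rose (4 fell adjusted over the list alone, and with the block 4 fell and 2 rose; camera adjusted p = 0.0787, and 0.0331 without HIGH 3). ABCA1, a cholesterol exporter, fell from 6.79 ± 2.66 to 0.135 ± 0.127 CPM, and ABCA2 fell 2.99-fold. The log2 fold change of ABCA1 was -6.71 without HIGH 3. Of 29 genes that transport or process nucleoside drugs or modify DNA methylation 2 fell and none rose (3 adjusted over the list alone, and with the block 6 fell and 6 rose; camera adjusted p = 0.619). TET1, a methylcytosine dioxygenase, had no count in HIGH and was at least 79.3-fold lower, and the nucleoside transporter SLC28A3 fell 4.45-fold. Of 55 genes of G1/S and DNA replication, the cyclin genes CCND1 and CCND2 fell 8.41-fold and 2.31-fold and none rose, also adjusted over the list alone, while with the block 7 fell and 5 rose (camera adjusted p = 0.486). That list was called lower without LOW 1 and higher without HIGH 1 (0.0131 and 0.0486). The proliferation marker MKI67 was at 512 ± 187 and 465 ± 109 CPM (edgeR adjusted p = 0.972). ABCA2 missed the threshold without LOW 1, LOW 2 or HIGH 3 (adjusted p = 0.0518, 0.0507 and 0.0703), CCND1 without LOW 2, LOW 3, HIGH 2 or HIGH 3 (0.0576, 0.0639, 0.0533 and 0.0508), and CCND2 without any single library other than LOW 3 (0.0622 to 0.154), with a filter at a mean of 5 CPM (0.0597) and without both libraries numbered 1 (0.0803). SLC28A3 missed it without any single library other than LOW 1 (0.0725 to 0.157) and without both numbered 1 (0.0547).

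HLA-DRA was the only member called among 7 tested MHC class II genes (5 fell adjusted over the list alone, and with the block 5 fell and 1 rose). The list's median log2 fold change was -1.54 (camera adjusted p = 0.00143, and adjusted p = 0.333 with an estimated correlation). Among 22 genes of MAPK and cytokine signalling output 3 fell and none rose, also adjusted over the list alone, and with the block 6 fell and 1 rose (camera adjusted p = 0.0345, and adjusted p = 0.683 with an estimated correlation). The phosphatase gene DUSP4 fell from 70.4 ± 5.74 to 20.5 ± 6.23 CPM. That list missed the threshold without LOW 2 or HIGH 1 (camera adjusted p = 0.156 and 0.235), with a filter at a mean of 5 CPM (0.0505) and without both libraries numbered 1 (0.0744). Of 27 hypoxia response genes, EGLN3, an oxygen-sensing prolyl hydroxylase, and LOX, a lysyl oxidase, had no count in HIGH and were at least 66.6-fold and 139-fold lower, and none rose (also adjusted over the list alone, and with the block 3 rose and 2 fell; camera adjusted p = 0.545). LOX missed the threshold without LOW 3 (edgeR adjusted p = 0.0511).

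Lists of growth and stress genes were called higher with few or no members called. They were the tricarboxylic acid cycle (28 tested), glutathione and NRF2 targets (25), MYC targets (44), mitochondrial ribosomal proteins (74) and heat shock proteins (21). HSPA6 alone rose among them and none fell, also adjusted over the list alone, while with the block 6, 7, 7, 15 and 7 members rose and 2, 1, 0, 1 and 1 fell. Their median log2 fold changes were 0.10, 0.28, 0.28, 0.14 and 0.35, and that of the tricarboxylic acid cycle turned to -0.0013 when scaled by library size alone. Camera's adjusted p were 0.0345, 0.00854, 0.0489, 0.0047 and 0.019, and none held with an estimated correlation (adjusted p = 0.337, 0.683, 0.797, 0.708 and 0.683). Each call was lost without LOW 1 (camera adjusted p = 0.112, 0.0759, 0.929, 0.0759 and 0.206) and without HIGH 2 (0.0627, 0.104, 0.966, 0.443 and 0.141), that of MYC targets also without HIGH 3 (0.282) and that of mitochondrial ribosomal proteins also without LOW 3 (0.0568). Without LOW 1 and without HIGH 2 the camera test of MYC targets turned in sign, with no shift detected. The tricarboxylic acid cycle also missed the threshold with upper-quartile scaling, library-size scaling, a filter at a mean of 5 CPM and without both libraries numbered 1 (camera adjusted p = 0.0671, 0.0807, 0.138 and 0.109), and MYC targets with that filter and without the 164 genes nearly absent from HIGH (0.114 and 0.0587). Between both libraries numbered 1 and the other 4, the medians of glutathione and NRF2 targets, MYC targets, mitochondrial ribosomal proteins and heat shock proteins were -0.40, -1.34, -0.44 and -0.86, larger in size than between HIGH and LOW (camera adjusted p = 0.0084, 7.18e-16, 0.000468 and 0.00116, and adjusted p = 0.871, 0.855, 0.913 and 0.871 with an estimated correlation). That grouping was taken from these same data, so its p-values describe it and do not test it.

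Over all 44 lists fixed before the data were examined, camera called 9 higher and 11 lower in HIGH, and 1 of these 20 calls, that of the LSC17 genes, held with an estimated correlation. By fry none of the 9 called higher passed, with adjusted p from 0.0778 for lysosome and autophagy to 0.823 for MYC targets. The 11 called lower all passed by fry except p53 targets (0.0508) and MAPK and cytokine signalling output (0.28). With the replicate block all 20 were called again among 25. The 5 gained were interferon response and lipid storage, described above, sorting stress and immediate early genes, the unfolded protein response and replication-dependent histones (camera adjusted p = 0.0262, 0.0221 and 0.0432 for the last 3, and adjusted p = 0.566, 0.588 and 0.577 with an estimated correlation). Among the lists that missed the threshold without the block, NF-kB and inflammatory genes had 2 falls among 23, and sorting stress and immediate early genes had 1 rise and 1 fall among 25, with the same counts adjusted over the list alone (with the block 3 rises and 2 falls, and 8 and 2; camera adjusted p = 0.576 and 0.0603). No member passed in the lists of cholesterol synthesis, glycolysis, the pentose phosphate pathway, mitochondrially encoded oxidative phosphorylation, serine, glycine and one-carbon metabolism, the unfolded protein response, G2/M, replication-dependent histones, cytosolic ribosomal proteins, MHC class I or apoptosis regulators, also adjusted over the list alone. Their camera adjusted p ran from 0.0521 for G2/M genes to 0.924 for the mitochondrially encoded genes. With 1 library fewer, camera called some lists of this paragraph higher. Without HIGH 1 these were sorting stress, the unfolded protein response, the pentose phosphate pathway and one-carbon metabolism (0.0343, 0.0486, 0.0212 and 0.0308), and without LOW 1 histones and cytosolic ribosomal proteins (0.0368 and 0.00011). Without LOW 2 they were sorting stress, the unfolded protein response and G2/M (0.0102, 0.00453 and 0.0406), without LOW 3 G2/M (0.00613) and without HIGH 2 cholesterol synthesis (0.0163). Without HIGH 3 they were sorting stress, G2/M, histones and cytosolic ribosomal proteins (0.0103, 0.00346, 0.0016 and 0.00013), and without both libraries numbered 1 the pentose phosphate pathway (0.0353). Upper-quartile and library-size scaling called sorting stress (0.0342 and 0.0275) and histones (0.0449 and 0.0338), RLE scaling G2/M (0.0489), and no filter sorting stress and G2/M (0.0451 and 0.0282). With the block, glycolysis had 6 rises and 1 fall, one-carbon metabolism 6 and 2, cytosolic ribosomal proteins 6 and 1, MHC class I 5 and 1, and G2/M 4 and 2. Over all 15826 tested genes the block called 1442 rises and 1785 falls. No count of members called with the block was tested against that share. Between both libraries numbered 1 and the other 4, camera called 14 lists, with cytosolic ribosomal proteins (median 0.66, adjusted p = 7.18e-16) and G1/S and DNA replication genes (-0.95, 1.72e-12) among the strongest beside MYC targets. This grouping was chosen after the same libraries were seen to stand apart, so its p-values describe it and do not test it. Glycolysis, one-carbon metabolism, histones and the pentose phosphate pathway were called too (medians -0.66, -0.52, 1.28 and -0.42, adjusted p = 0.000468, 0.0084, 0.0084 and 0.0466). The calls also included haematopoietic stem cell genes, stromal and endothelial genes, MAPK and cytokine signalling output and fatty acid uptake (medians 0.54, 1.01, -0.56 and -0.60, adjusted p = 0.00876, 0.0275, 0.0461 and 0.0239), and none of the 14 held with an estimated correlation (adjusted p from 0.799 to 0.913).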

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

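The fits without both libraries numbered 1, the lists without the genes nearly absent from HIGH, and the block with an estimated correlation were chosen after seeing the data. With the replicate number as a block, 3227 genes differed (1442 higher, 1785 lower), and the 816 genes called without it were all among them with their directions. A filter at a mean of 5 CPM, which tested fewer genes, left 241 (32 higher, 209 lower), and DESeq2 called 251 higher. Leaving out 1 library gave 527 to 840 differing genes, 26 to 90 higher and 485 to 750 lower, each with fewer samples. No gene called in the unblocked fit changed sign in any of these fits. Of the lists, 1 was called with an estimated correlation, 13 with fry and 0 with the block and an estimated correlation together. For the last, 1 list had an unadjusted p under 0.05. The residual degrees of freedom were 4 without and 2 with the block. Estimated correlations of LSC17 and dendritic cell genes were -0.004 and -0.053, below the preset 0.01. Their unadjusted camera p without the block still went from 7.12e-19 to 0.000689 and from 2.45e-06 to 0.00743. This argues against a raised correlation as the cause in these lists, while that of MYC targets was estimated at 0.914. Camera with an estimated correlation also uses the residual degrees of freedom in place of the number of genes. This raises p even where the correlation is not raised. How much of the rise in the other lists comes from this was not tested. Scaling by library size alone put the median log2 fold change of all tested genes at -0.08, against 0.03 with TMM, and that of the tricarboxylic acid cycle at -0.0013. SCD, not called anywhere, was at 0.012 with RLE scaling and with DESeq2. Over the fits without 1 library, SCD ran from -0.25 to 0.30 and MKI67 from -0.41 to 0.055. In the same fits the adjusted p of MYC targets ran from 3.84e-08 to 0.966, with reversed direction at 0.929 and 0.966, and its median from -0.052 to 0.66 (between both libraries numbered 1 and the others it was -1.34); the median log2 fold change of mitochondrial ribosomal proteins ran from -0.00693 to 0.36. The cause was not tested.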

Other observations

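The HOX genes were counted by cluster after their values were seen, and the tests on genes nearly absent from HIGH, on shared replicate numbers and on zinc finger genes were likewise chosen after the result was seen. All 8 tested HOXB genes fell in HIGH, with and without the replicate block. HOXB4, a regulator of stem cell self-renewal, stood at 3.90 ± 0.801 CPM in LOW (SD, n = 3) and had no count in HIGH, which puts it at least 131-fold lower, and HOXB2 was at least 93.2-fold lower. Of 11 HOXA genes 2 fell, HOXA7 (log2 fold change -2.97, SE 0.44) and HOXA5 (-1.62, SE 0.33), and 5 fell with the block. HOXA10 was at 126 ± 29.5 and 162 ± 8.14 CPM (edgeR adjusted p = 0.694). Of 7 HOXC genes none fell, and 1 fell with the block. HOXA5 missed the threshold without any single library other than HIGH 1 (adjusted p from 0.0906 to 0.156) and with a filter at a mean of 5 CPM (0.0794). Antisense transcripts overlap these genes and were not told apart from them.

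The 164 genes read in every LOW library and nearly absent from HIGH lay on many chromosomes, and no autosome or X chromosome had more than 1.99% of its tested genes among them, which argues against the loss of a few chromosomes. The HIGH libraries had 0.888 times the depth of the LOW libraries, too close to account for the absence. The genes were shifted together among the LOW libraries, with a median log2 ratio of LOW 1 to LOW 2 and 3 of 0.74, above the upper limit of 0.21 of the central 95% of 10000 lists matched on expression. LOW 2 and LOW 3 differed by 0.07, and both libraries numbered 1 stood apart in many other genes. Either a second cell population whose share differed between LOW libraries or a shift shared by the libraries numbered 1 would thus give the value of 0.74. The ratios of single genes spread, with quartiles of 0.37 and 1.11. Their SD was 0.60, against 0.76 in the genes from which the matched lists were drawn. Only the median was tested, not whether the genes shared 1 ratio. A minor share beside cells like those in HIGH would leave few rises above 2-fold, and 35 genes rose by significantly more than that, so such a share alone cannot account for both directions. Whether LOW cells form one state or several was not tested.

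Both libraries numbered 1 stood apart from the other 4. Across genes, their deviation had a Spearman correlation of -0.0103 with transcript length and 0.0335 with GC content over 15058 genes, which argues against either bias; genes are not independent replicates. Deviations of libraries with equal numbers correlated at 0.44 or more, and those of other pairs at 0.18 or less, as a culture, day or batch shared by equal numbers would give. The low values are not separate evidence, because deviations within a group cancel out. Between these 2 and the other 4 libraries, 1826 genes were higher and 2166 lower, but the grouping was taken from these same data.

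Zinc finger genes were frequent among the falls, with 90 of 458 tested lower in HIGH and none higher, and with the block 181 lower and 7 higher. Lists matched on expression had up to 41 falls in their central 95%, which argues against low expression as the cause. The count was 12 with a filter at a mean of 5 CPM, which tested fewer genes, and 56, 57 and 53 without LOW 3, HIGH 2 and HIGH 3. On chromosome 19, 70 of 230 zinc finger genes fell, against 30 of 932 other genes, and elsewhere 20 of 228 zinc finger genes fell (odds ratio 2.18, against 5.62 for all zinc finger genes). Reads shared between paralogs were not tested, and no biological explanation was tested.

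The 6 libraries can be split into groups of 3 in 10 ways, too few for a share under 0.05. The real split called 816 genes, and the highest of the others 0. Each other split mixes LOW and HIGH, so the large differences widen the spread within its groups. Few gene calls were therefore likely in them from the start, and the contrast in genes decides little. The real split called 20 gene lists, and the highest of the others 18. Of the 10 splits, 1 called as many genes as the real one and 1 as many lists, the real split itself in both. The splits that, like the real one, part all 3 pairs of equal numbers called 18, 17 and 11 lists, so a camera count near 20 also arises between groups that mix LOW and HIGH.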
